A study of Mus musculus with 24 samples.

How the data were processed

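RNA was measured in 3 kinds of projection neuron sorted by FACS from the cortex of CD1 mice, an outbred laboratory strain, at 4 stages: embryonic days 15, 16 and 18 (E15, E16, E18) and postnatal day 1 (P1). Callosal projection neurons connect the cerebral hemispheres, subcerebral projection neurons send axons to the brainstem and spinal cord, and corticothalamic projection neurons send axons to the thalamus. The labels list 24 libraries, 2 for each of the 12 combinations of stage and subtype. Per the labels' protocols, RNA was recovered with a kit for total nucleic acid after a proteinase K digestion, its integrity number lay between 6.3 and 9, a sorted event yielded 1 to 2 pg of RNA, about 100000 cells gave the 200 ng used as input, and libraries were made with poly(A) selection. The antibodies or markers used for sorting are not given in the sources used here, nor whether the libraries of a group came from separate animals.

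The values are in a single table of 32310 entries by 12 columns, 1 column per stage and subtype, with no column per library. Per the submitters' processing notes, TopHat2 and Cufflinks were used with the mouse genome build mm9; versions, annotation, filters, scaling and the way the 2 libraries of a group were combined are not given in the sources used here. The header names no unit. The deposited values were read as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of a library), an inference from the use of Cufflinks, from values that are never negative and often far below 1, and from column sums that differ between groups. FPKM values keep no read counts, so the depth behind each value is unknown, no counting interval can be given, and reads shared between overlapping genes or near-identical copies cannot be separated; whether strand was used is not given either. The column sums ran from 355965 to 473871, and the 50 most abundant entries took between 13% and 19.5% of a column. Entries whose names start with XLOC_ are loci known only by an assembly identifier; they made up 4438 of the entries. A value of exactly 0 is called "listed at 0", since it can be a failed estimate, and no fold at a single stage is given against it. Means over stages or subtypes can include such values, as for Fam19a1, which was listed at 0 in 2 groups. Gene names are used as the table gives them, with older symbols of list members looked up in the RefSeq gene table of GRCm38.p6; no coordinates are given, since that assembly is not the one named by the submitters.

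The design fixed before the data were examined assumed a value for each library. Since the table holds 1 value per group, the fallback written with that design was used: limma-trend (limma 3.58.1, statmod 1.5.0, R 4.3.3; lmFit, contrasts.fit and eBayes with a variance trend and robust moderation) on log2(FPKM + 1), with additive terms for stage and subtype over the 12 values and 6 residual degrees of freedom. The residual of this model is the interaction of subtype with stage. A subtype comparison therefore rests on 4 values per subtype, and a stage comparison on 3 values per stage; the p-values measure how evenly a difference held over the other stages or subtypes, not the spread between libraries, and a gene whose subtype difference changed with stage has a large error. Pairs of subtypes at a single stage, and the interaction itself, have values and no test. A stage comparison cannot be told apart from a difference in collection, preparation or sequencing shared by all groups of a stage. Log2 fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes, and are given ± the standard error of the fit. Genes with at least 1 FPKM in at least 2 columns were tested, 13946 in all, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. A gene was called highest in a subtype where it passed, in the higher direction, in both comparisons with the other subtypes.

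Of the gene lists, 29 were fixed before the data were examined, from prior knowledge of cortical neurons that can include earlier descriptions of these cell types. They covered callosal, subcerebral and corticothalamic neuron genes, subplate genes, proliferating cells and progenitors, interneurons, Cajal-Retzius cells, astrocytes and radial glia, the oligodendrocyte lineage, microglia, vascular cells, red blood cells, the netrin and slit pathway, semaphorins and plexins, ephrins and Eph receptors, cadherins, synaptic vesicle and release genes, glutamate receptors and the postsynaptic density, voltage-gated channels, GABA receptors and chloride transport, migration and early neuronal differentiation, immediate early genes, heat shock and stress genes, cholesterol synthesis, known long noncoding RNAs, retinoic acid and Wnt signalling, cytosolic ribosomal proteins, nuclear respiratory chain genes and mitochondrially encoded genes. A list needed 3 tested members, which the red blood cell and mitochondrially encoded lists did not reach. The others were tested with camera at its preset correlation of 0.01, in the 3 subtype comparisons and in P1 minus E15, with adjustment over these 108 tests. None of the 27 calls held when camera estimated the correlation within each list; the lowest adjusted p was then 0.0654. The rotation test fry, which asks whether a list's genes moved on balance in a single direction, gave 45 calls. Counts of list members that passed are to be read against all 13946 genes tested. Of these, 4093 passed in callosal minus subcerebral, 4361 in callosal minus corticothalamic, 3835 in subcerebral minus corticothalamic and 9400 in P1 minus E15.

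Genes were named by a rule fixed before the data were examined: marker genes such as Bcl11b and Tle4 throughout; the 10 largest changes in each direction for each subtype comparison and for P1 minus E15, among genes that passed, had the same sign at every stage (or in every subtype) and reached a mean of 5 FPKM in the higher group; the 3 largest in each direction for each single-stage pair and each step between stages; the 10 largest for the interaction; the 10 with the largest smaller fold among genes highest in a subtype; and, of each list, up to 4 members with the smallest p and any that passed against the list's majority. Some genes that the rule names are not reported here. Genes chosen after their values were seen are named as such.

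The fit was tested on simulated data, drawn with the means and spreads of the real genes, in which 67, 67 and 66 genes were changed by 0.5, 1 and 2 on the log2 scale. For callosal minus subcerebral 58.2%, 85.1% and 97% of them were recovered, for callosal minus corticothalamic 58.2%, 88.1% and 93.9%, and for subcerebral minus corticothalamic 58.2%, 83.6% and 98.5%. The shares were 40.3%, 86.6% and 98.5% for E16 minus E15, 52.2%, 83.6% and 97% for E18 minus E16, 41.8%, 76.1% and 97% for P1 minus E18, and 50.7%, 91% and 95.5% for P1 minus E15. Of the calls in these comparisons, in the order given, unchanged genes made up 12 of 172, 8 of 168, 10 of 170, 13 of 163, 12 of 167, 7 of 150 and 14 of 172, or 4.7% to 8.1%, above the threshold of 5% in 5 of the 7 comparisons. The simulated errors were independent, so these shares do not cover an interaction shared by many genes. All other genes were given no difference, whereas the real comparisons called 620 to 9400 genes. The errors of a gene also had the same spread in every group. The shares therefore need not hold for the real comparisons.

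The alternatives tried were a pseudocount of 0.1, no filter beyond a value above 0 in 2 columns, a filter at 5 FPKM, median-ratio scaling over genes above 1 FPKM in every column, quantile normalization, eBayes without trend and robust moderation, each stage or subtype left out in turn, and a fit on the 8 values of the compared subtypes. Fits without the E15 callosal, E16 callosal or E15 subcerebral value, lists without E15 or without the E15 callosal value, and the interaction without short RNA and AK identifiers were added after the data were seen. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.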

Results

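The table gave an expression value in FPKM for 32310 genes and loci in 12 groups: callosal, subcerebral and corticothalamic projection neurons of the mouse cortex, each at E15, E16, E18 and P1. Each value is the authors' pooled value for the 2 libraries of a group, so it has no SD or n of its own, and its sequencing depth is unknown. Between 12294 and 12838 genes per group reached 1 FPKM, and between 10222 and 11064 were listed at 0. In all, 7740 genes were listed at 0 in every group and 13946 were tested. Fold changes between subtypes are means over the 4 stages and fold changes between stages are means over the 3 subtypes, on the log2(FPKM + 1) scale with the standard error (SE) of the limma fit.

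Marker genes of subcerebral and corticothalamic neurons were read as a check of the labels. The sort markers are not given. If the sort used the products of these genes, their differences would follow from it and give no independent support. Bcl11b, which encodes the zinc finger transcription factor CTIP2, was highest in subcerebral neurons at every stage, at 168, 124, 109.5 and 104 FPKM from E15 to P1. It was 97.1, 68.0, 36.7 and 32.1 FPKM in corticothalamic neurons, and at most 6.94 FPKM in callosal neurons. Tle4, which encodes a Groucho-family corepressor, stayed between 192 and 212 FPKM in corticothalamic neurons, while it was 65.3 FPKM in subcerebral neurons at E15 and 11.3 FPKM at P1. In callosal neurons Tle4 did not exceed 3.16 FPKM.

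**Figure D1:**
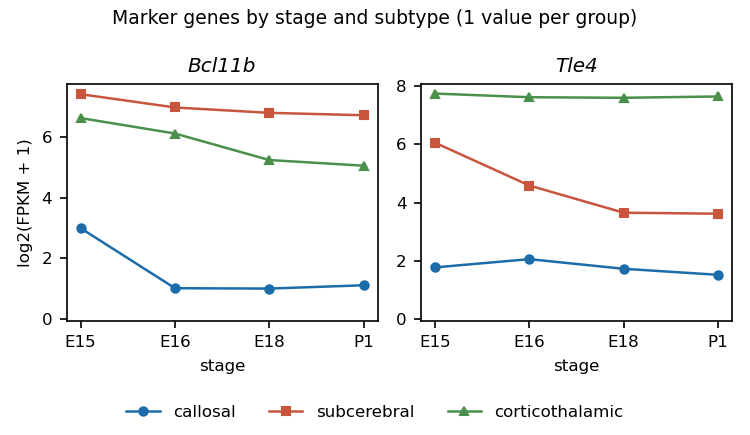
Log2(FPKM + 1) of Bcl11b and Tle4 at each stage, with 1 line per subtype and 1 pooled value per point. Bcl11b is highest in subcerebral neurons at every stage and Tle4 in corticothalamic neurons.

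Callosal and subcerebral neurons were compared to find genes that separate neurons joining the hemispheres from neurons projecting to the brainstem and spinal cord. Genes for the homeobox transcription factors Cux2, Cux1 and Lhx2 were higher in callosal neurons. Cux2 was higher by 4.73 ± 0.20 (limma adjusted p = 1.36e-05), Cux1 by 3.58 ± 0.18 (limma adjusted p = 3.27e-05) and Lhx2 by 4.18 ± 0.29 (limma adjusted p = 9.22e-05). The largest callosal differences also included those of netrin-G2 (Ntng2, 4.53 ± 0.41), the semaphorin receptor plexin A4 (Plxna4, 4.44 ± 0.45), fibronectin (Fn1, 4.23 ± 0.22), an activin subunit (Inhba, 3.92 ± 0.16), Shisa2 (3.46 ± 0.14) and the adhesion molecule Mdga1 (3.44 ± 0.72), with 9130024F11Rik at 3.35 ± 0.39. In the other direction Bcl11b differed by -5.44 ± 0.26 (limma adjusted p = 2.26e-05), and Kif26a, a member of the kinesin family, by -5.25 ± 0.08 (limma adjusted p = 1.26e-08). Crym, which encodes a thyroid hormone-binding protein, differed by -4.90 ± 0.51, and Islr2 by -4.31 ± 0.24. Tcerg1l differed by -4.30 ± 1.01, the natriuretic peptide receptor gene Npr3 by -3.58 ± 0.34 and the synaptic adhesion gene Lrrtm4 by -3.42 ± 0.34. Ddah1 differed by -3.39 ± 0.48, the neurexophilin gene Nxph3 by -3.24 ± 0.44 and Iqcj-schip1 by -3.22 ± 0.40. Tle4 differed by -2.71 ± 0.38 (limma adjusted p = 0.00214). In all, 4093 genes passed, 1968 higher and 2125 lower in callosal neurons, with 299 in each direction at least 2-fold apart. The share higher was 48.1%, against 50.2% with median-ratio scaling, 51.4% with quantile normalization, 51.4% with no filter and 51.2% without E18. The count was 6179 without E15, 1117 without E16, 1016 without E18, 2230 without P1, 2174 without the E16 callosal value and 2606 in a fit on the 8 values of these subtypes. Of the 20 genes with the largest differences, 18 passed whichever stage was left out, while Mdga1 and Tcerg1l had adjusted p of 0.0736 and 0.112 without E16, 0.0919 and 0.114 without E18, and 0.0623 and 0.0756 without P1.

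The callosal and subcerebral lists moved toward the subtype they are named for, and the corticothalamic list was lower in callosal than in subcerebral neurons. Of 26 tested callosal neuron genes, 18 were higher in callosal than in subcerebral neurons and 0 lower (19 and 0 adjusted over the list alone), with a median of 2.03 (camera adjusted p = 1.9e-11; adjusted p = 0.0654 with an estimated correlation). Among them Ptn, which encodes the growth factor pleiotrophin, was higher by 2.86 ± 0.17. Of 22 subcerebral neuron genes, 14 were lower in callosal neurons (15 adjusted over the list alone), including Fezf2, a zinc finger transcription factor gene, at -3.08 ± 0.28, and the G-protein regulator gene Rgs4 at -2.57 ± 0.29. The ephrin receptor gene Epha4 was the exception, at 1.36 (limma adjusted p = 0.0453). That list had camera adjusted p = 1.49e-06, and adjusted p = 0.354 with an estimated correlation. Of 19 corticothalamic neuron genes, 11 were lower in callosal neurons (12 adjusted over the list alone), among them Foxp2 at -2.18 ± 0.18 and Sox5 at -1.76 ± 0.22, and Ntsr1 was higher by 0.69 (limma adjusted p = 0.016). That list had camera adjusted p = 0.000102 (adjusted p = 0.354 with an estimated correlation). Genes of proliferating cells and progenitors were higher in callosal neurons in 9 of 22 cases and lower in 1 (9 and 1 adjusted over the list alone), with Neurog2 at 1.14 ± 0.18 and the intermediate filament gene Nes at 0.86 ± 0.14 (camera adjusted p = 0.0023; adjusted p = 0.354 with an estimated correlation). Microglial genes moved with these groups: 9 of 11 were higher in callosal neurons (9 higher and 1 lower adjusted over the list alone), with a median of 1.48 (camera adjusted p = 0.00119; adjusted p = 0.808 with an estimated correlation). Nuclear genes of the respiratory chain were lower in callosal neurons in 15 of 87 cases and higher in 1 (0 and 0 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 6.69e-05, or 0.869 with an estimated correlation). The share of this list that passed was smaller than over all genes tested (4093 of 13946).

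Axon guidance genes differed between callosal and subcerebral neurons in both directions. Camera called none of the 3 lists, while fry called each as higher in callosal neurons (fry adjusted p = 0.0108 for each). In the netrin and slit pathway 9 of 17 genes were higher in callosal neurons and 3 lower (9 and 4 adjusted over the list alone; camera adjusted p = 0.102). The netrin receptor gene Unc5c was higher by 2.45 ± 0.38, and the repulsive ligand gene Slit1 differed by -1.87 ± 0.29. Of 28 semaphorin and plexin genes, 8 were higher and 4 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.267), with Sema6a at -1.62 ± 0.21 and Sema5b at 1.27 ± 0.16. Of 19 ephrin and Eph receptor genes, 7 were higher and 3 lower (8 and 3 adjusted over the list alone; camera adjusted p = 0.0838). The receptor genes Epha3 and Ephb1 stood at opposite ends of that list, at 3.30 ± 0.24 and -3.09 ± 0.15. Synaptic vesicle genes were lower in callosal neurons in 10 of 29 cases and higher in 2 (10 and 2 adjusted over the list alone; camera adjusted p = 0.0847; fry adjusted p = 0.0329), with the vesicle fusion gene Snap25 at -1.06 ± 0.12 and the vesicular glutamate transporter gene Slc17a6 at 3.02 ± 0.33.

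**Figure D2:**
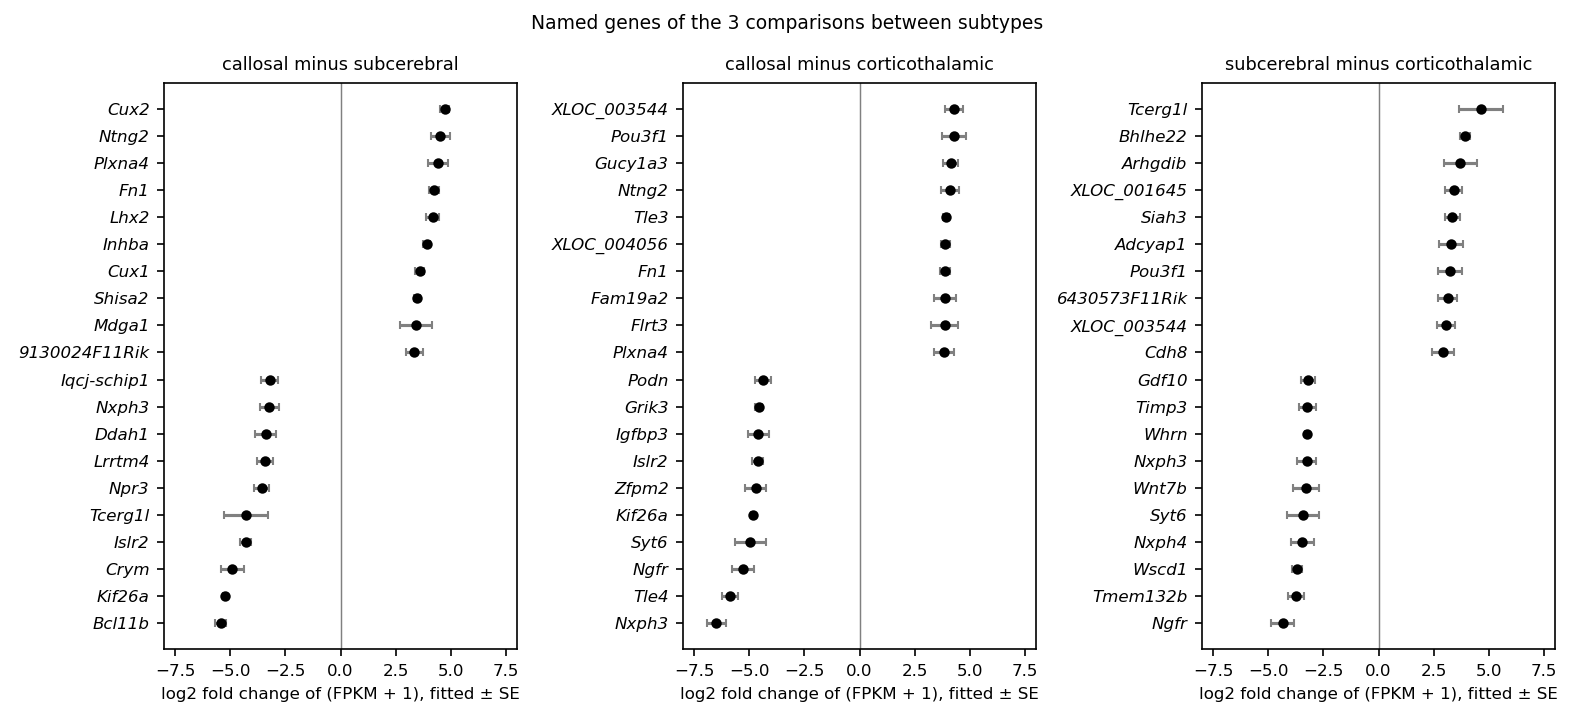
Fitted log2 fold change of FPKM + 1, with standard errors as bars, for the 10 largest differences in each direction in each comparison between subtypes. The differences run from -6.51 for Nxph3 (callosal minus corticothalamic) to 4.73 for Cux2 (callosal minus subcerebral).

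Between callosal and corticothalamic neurons the largest differences were in genes higher in corticothalamic neurons. The neurexophilin gene Nxph3 was lower in callosal neurons, by a log2 difference of -6.51 ± 0.44 (limma adjusted p = 4.54e-05), followed by Tle4 at -5.87 ± 0.38 (limma adjusted p = 4.07e-05) and Ngfr, the p75 neurotrophin receptor gene, at -5.28 ± 0.52 (limma adjusted p = 0.000246). The synaptotagmin gene Syt6 differed by -4.95 ± 0.71, Kif26a by -4.84 ± 0.08, the transcriptional cofactor gene Zfpm2 by -4.72 ± 0.48 and Islr2 by -4.63 ± 0.24. For the remaining genes the differences were smaller: the insulin-like growth factor binding protein gene Igfbp3 by -4.59 ± 0.48, the kainate receptor gene Grik3 by -4.57 ± 0.17 and Podn by -4.39 ± 0.35. In the other direction XLOC_003544 was higher by 4.28 ± 0.42 and the POU-domain transcription factor gene Pou3f1 by 4.28 ± 0.53 in callosal neurons. The guanylate cyclase subunit gene Gucy1a3 was higher by 4.13 ± 0.35, Ntng2 by 4.12 ± 0.41, the corepressor gene Tle3 by 3.92 ± 0.12 and XLOC_004056 by 3.89 ± 0.19. Fn1 was higher by 3.89 ± 0.22, Fam19a2 by 3.88 ± 0.49, the adhesion gene Flrt3 by 3.86 ± 0.60 and Plxna4 by 3.85 ± 0.45. Bcl11b differed by -4.22 ± 0.26 (limma adjusted p = 3.12e-05). In all, 4361 genes passed, 2132 higher and 2229 lower in callosal neurons, with 361 and 496 at least 2-fold apart. The share higher was 48.9%, against 44.9% with median-ratio scaling, 51.9% with quantile normalization and 51.2% with the filter at 5 FPKM. The count was 1868 without E16, 2024 without E18 and 2812 without the E16 callosal value. All 20 of the genes with the largest differences passed whichever stage was left out.

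Of 19 tested corticothalamic neuron genes, 18 were lower in callosal than in corticothalamic neurons (18 adjusted over the list alone), with a median of -2.43 (camera adjusted p = 3.1e-11; adjusted p = 0.144 with an estimated correlation). Foxp2, a forkhead transcription factor gene, differed by -4.22 ± 0.18 and Sox5 by -2.39 ± 0.22. Callosal neuron genes were higher in 16 of 26 cases and lower in 0 (18 and 0 adjusted over the list alone), with Ptn at 3.83 ± 0.17 and Inhba at 3.78 ± 0.16 (camera adjusted p = 9.46e-09; adjusted p = 0.0705 with an estimated correlation). Genes of cholesterol synthesis were higher in callosal neurons in 11 of 20 cases and lower in 0 (13 and 0 adjusted over the list alone), with a median of 0.61 (camera adjusted p = 0.000102; adjusted p = 0.808 with an estimated correlation). Among them were Cyp51 at 0.90 ± 0.18 and Lss at 0.78 ± 0.14. Cytosolic ribosomal protein genes were higher in 21 of 75 cases (21 adjusted over the list alone), with Rpl3 at 0.46 ± 0.07 and Rps2 at 0.46 ± 0.07 (camera adjusted p = 3.19e-05; adjusted p = 0.869 with an estimated correlation). Nuclear respiratory chain genes were higher in 9 of 87 cases and lower in 1 (4 and 0 adjusted over the list alone; camera adjusted p = 0.018; adjusted p = 0.869 with an estimated correlation). That call ended with quantile normalization (adjusted p = 0.0745), without E15 (0.209) and without the E15 callosal value (0.5). The shares of the ribosomal protein and respiratory chain lists that passed were smaller than over all genes tested (4361 of 13946). Microglial genes moved with the callosal groups here too: 9 of 11 were higher and 1 lower (9 and 1 adjusted over the list alone), with a median of 1.39 (camera adjusted p = 0.00241; adjusted p = 0.808 with an estimated correlation).

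Other groups split between callosal and corticothalamic neurons without a call by camera. Of these, fry called subplate genes (fry adjusted p = 0.00217), subcerebral neuron genes (0.046) and glutamate receptor genes (0.0102) as lower in callosal neurons and migration genes (4.8e-05) as higher, and did not call cadherins (0.814) or GABA receptor genes (0.756). Of 13 subplate genes, which mark the deepest and earliest-born cortical neurons, 6 were lower and 3 higher in callosal neurons (9 and 3 adjusted over the list alone; camera adjusted p = 0.0512, and 0.0468 with quantile normalization, or 0.443 there with an estimated correlation), with the potassium channel subunit gene Kcnab1 at -2.82 ± 0.24 and Nxph4 at -4.18 ± 0.51. Subcerebral neuron genes were lower in 7 of 22 cases and higher in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0642, 0.0472 without E15 and 0.00928 without the E15 callosal value, or 0.567 and 0.582 there with an estimated correlation), with the transcription factor gene Bhlhe22 at 2.92 ± 0.23 as the exception. Migration and early differentiation genes were higher in 9 of 30 cases and lower in 2 (12 and 2 adjusted over the list alone; camera adjusted p = 0.0707, and 0.0379 without E15, or 0.567 there with an estimated correlation), with Islr2 and Sox5 as the lower ones. The mean of this list was 0.06, and -0.05 with quantile normalization. Among 23 cadherin genes 5 were higher and 6 lower (5 and 6 adjusted over the list alone; camera adjusted p = 0.797), with Pcdh8 at 3.25 ± 0.20 and Cdh11 at -1.54 ± 0.17. Among 15 genes of GABA receptors and chloride transport 3 were higher and 4 lower (3 and 6 adjusted over the list alone; camera adjusted p = 0.662), with the receptor subunit gene Gabra2 at 3.04 ± 0.23. Of 38 genes of glutamate receptors and the postsynaptic density, 4 were higher and 9 lower (6 and 9 adjusted over the list alone; camera adjusted p = 0.239), with the metabotropic receptor gene Grm2 at 3.33 ± 0.17. Of the axon guidance lists, ephrins and Eph receptors had 9 higher and 2 lower of 19 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0838; fry adjusted p = 0.00212, toward higher). The netrin and slit pathway had 6 higher and 3 lower of 17 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0898; fry adjusted p = 0.0144, toward higher). Semaphorins and plexins had 7 higher and 5 lower of 28 (8 and 6 adjusted over the list alone) and were called by neither test (camera adjusted p = 0.901; fry adjusted p = 0.585).

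Subcerebral and corticothalamic neurons, which both send axons out of the cortex to deep targets, were compared to find genes that separate them. Tcerg1l was higher in subcerebral neurons by 4.65 ± 1.01 (limma adjusted p = 0.0151), Bhlhe22 by 3.91 ± 0.23 (limma adjusted p = 0.000183), Arhgdib by 3.71 ± 0.77 and Siah3 by 3.35 ± 0.34. Adcyap1, which encodes the neuropeptide PACAP, was higher by 3.28 ± 0.55, Pou3f1 by 3.25 ± 0.53 and the cadherin gene Cdh8 by 2.92 ± 0.50, with XLOC_001645 at 3.42 ± 0.38, 6430573F11Rik at 3.13 ± 0.42 and XLOC_003544 at 3.07 ± 0.42. Ngfr differed by -4.36 ± 0.52 (limma adjusted p = 0.00222) and Whrn, which encodes the scaffold protein whirlin, by -3.24 ± 0.09 (limma adjusted p = 1.04e-06). Tmem132b differed by -3.73 ± 0.37, Wscd1 by -3.69 ± 0.22, Nxph4 by -3.46 ± 0.51, Syt6 by -3.42 ± 0.71, and the secreted signal gene Wnt7b by -3.31 ± 0.59. Nxph3 differed by -3.27 ± 0.44, the metalloproteinase inhibitor gene Timp3 by -3.23 ± 0.38 and the growth factor gene Gdf10 by -3.20 ± 0.32. Tle4 differed by -3.17 ± 0.38 (limma adjusted p = 0.00224). Bcl11b was 1.21 ± 0.26 higher in subcerebral neurons (limma adjusted p = 0.0142), but its adjusted p was 0.0538 without E16, 0.124 without E18 and 0.0841 without P1. In all, 3835 genes passed, 2048 higher and 1787 lower in subcerebral neurons, with 216 and 286 at least 2-fold apart. The share higher in subcerebral neurons was 53.4%, but 45.6% with median-ratio scaling, 49.1% with no filter, 40.9% without E16 and 41.4% without E18. The count was 6258 without E15, 330 without E16, 251 without E18, 1051 without P1, 6132 without the E15 subcerebral value and 2409 in a fit on the 8 values of these subtypes. Of the 20 genes with the largest differences, 10 passed whichever stage was left out. Of the others, 9 missed the threshold without E16, 9 without E18 and 5 without P1, with adjusted p up to 0.127 (Tcerg1l without E18). These were Tcerg1l, Arhgdib, Adcyap1, Pou3f1, Cdh8, XLOC_003544, 6430573F11Rik, Nxph4, Syt6 and Wnt7b.

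Of 87 nuclear respiratory chain genes, 42 were higher in subcerebral than in corticothalamic neurons and 0 lower (55 and 0 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 1.9e-11; adjusted p = 0.781 with an estimated correlation). Genes of cholesterol synthesis were higher in 14 of 20 cases and lower in 0 (17 and 0 adjusted over the list alone), with a median of 0.72 (camera adjusted p = 7.31e-06; adjusted p = 0.781 with an estimated correlation). Mvk was higher by 0.86 ± 0.14, with adjusted p of 0.0647 without E16 and 0.0828 without E18. Cytosolic ribosomal protein genes were higher in 11 of 75 cases (7 adjusted over the list alone), with Rps2 at 0.66 ± 0.07 (camera adjusted p = 5.56e-05; adjusted p = 0.869 with an estimated correlation). This call ended with quantile normalization, where the list's mean went from 0.16 to 0.01 and its adjusted p was 0.89. The share of this list that passed was smaller than over all genes tested (3835 of 13946). Of 22 subcerebral neuron genes, 9 were higher and 0 lower (9 and 0 adjusted over the list alone), with Diap3 at 1.06 ± 0.15 (camera adjusted p = 0.00754; adjusted p = 0.781 with an estimated correlation). Of 19 corticothalamic neuron genes, 11 were lower in subcerebral neurons and 1 higher (13 and 1 adjusted over the list alone), with Foxp2 at -2.03 ± 0.18 and the neurotensin receptor gene Ntsr1 at -1.47 ± 0.16, while Fezf2 was 1.00 higher (limma adjusted p = 0.0317). The list had camera adjusted p = 0.000164 (adjusted p = 0.354 with an estimated correlation). Subplate genes were lower in 8 of 13 cases and higher in 1 (9 and 1 adjusted over the list alone), with Kcnab1 at -2.94 ± 0.24 and the nicotinic receptor subunit gene Chrna5 at 1.28 (camera adjusted p = 0.00173; adjusted p = 0.354 with an estimated correlation). Genes of proliferating cells and progenitors were lower in 11 of 22 cases and higher in 0 (14 and 1 adjusted over the list alone), with the replication gene Mcm6 at -0.82 ± 0.15, whose adjusted p was 0.0608 without E16 and 0.0883 without E18. The list had a median of -0.28 (camera adjusted p = 0.0011; adjusted p = 0.354 with an estimated correlation). Interneuron genes were lower in subcerebral neurons in 1 of 14 cases (1 adjusted over the list alone; camera adjusted p = 0.127), with adjusted p of 0.00448 without E15 and 0.000196 without the E15 callosal value at the preset correlation, and 0.658 and 0.51 with an estimated correlation.

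A gene was highest in a subtype when it passed against both others. Callosal neurons had 985 such genes, led by Ntng2, Fn1, Plxna4, Inhba, Cux2, Lhx2, Cux1, 9130024F11Rik and the transcriptional repressor gene Bcl6, whose smaller difference lay between 4.12 and 3.10. Subcerebral neurons had 580, led by Tcerg1l (4.30), Adcyap1 (2.92), Fam19a1 (2.76), Pex5l (2.39), Arhgdib (2.36), XLOC_001645 (2.29), the sulfotransferase gene Chst8 (2.27), Siah3 (2.23), the adhesion gene Ncam2 (2.21) and Galntl6 (2.21). Corticothalamic neurons had 849, led by Ngfr (4.36), Nxph4 (3.46), Syt6 (3.42), Nxph3 (3.27), Whrn (3.24), Gdf10 (3.20), Tle4 (3.17), Tmem132b (3.11), Ppp1r1b, which encodes the phosphatase regulator DARPP-32 (2.96), and the Wnt inhibitor gene Apcdd1 (2.90). Several of the subcerebral genes were low at E15 and high later: Tcerg1l was 0.343 FPKM in subcerebral neurons at E15 and 81.3, 165 and 166 FPKM from E16 to P1, and Adcyap1 was 1.79 FPKM at E15 and 48.7 FPKM at E16. Of the 10 subcerebral genes, XLOC_001645, Chst8 and Siah3 passed in both comparisons whichever stage was left out, and of the 10 corticothalamic genes Nxph4, Syt6, Ppp1r1b and Apcdd1 did not. The callosal count was 311 without E16, 328 without E18 and 542 without the E16 callosal value. The subcerebral count was 1783 without E15, 39 without E16, 20 without E18, 104 without P1, 910 without the E15 callosal value, 254 without the E16 callosal value and 1693 without the E15 subcerebral value. The corticothalamic count was 156 without E16, 119 without E18 and 358 without P1.

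Pairs of subtypes at a single stage had 1 value each and no test. Subcerebral and corticothalamic neurons were at least 2-fold apart in 408 genes at E15, 691 at E16, 972 at E18 and 1162 at P1. Over the same stages callosal and subcerebral neurons were apart in 686, 889, 915 and 1053 genes, and callosal and corticothalamic neurons in 1148, 1074, 1005 and 1111. With a pseudocount of 0.1 the counts were 875, 1252, 1528 and 1856 for the first pair, 1305, 1538, 1593 and 1826 for the second, and 1852, 1730, 1596 and 1676 for the last. The genes named next were not listed at 0 in the groups compared. At E15 the largest difference of callosal over subcerebral neurons was that of Plxna4 (5.25), and the largest in the other direction were those of Kif26a (-5.10) and Nxph3 (-4.96). Between subcerebral and corticothalamic neurons at E15, Bhlhe22 led one direction (3.21) and Kitl, which encodes the KIT ligand, the other (-4.41). At P1 the same pair was led by Tcerg1l (6.76) and by Ngfr (-5.50) and Syt6 (-5.38). At E16 the largest differences included BC023483 (4.67, callosal over corticothalamic), and at E18 Fam19a1 (5.26, subcerebral over corticothalamic). Mdga1 was 67.3 and 62.5 FPKM in callosal and subcerebral neurons at E15, and 98.6 and 1.24 FPKM at P1. Many of the remaining largest values belonged to small RNAs such as Snora31, Snora15, Mir677 and Mir1966, which were listed at 0 in a compared group.

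**Figure D3:**
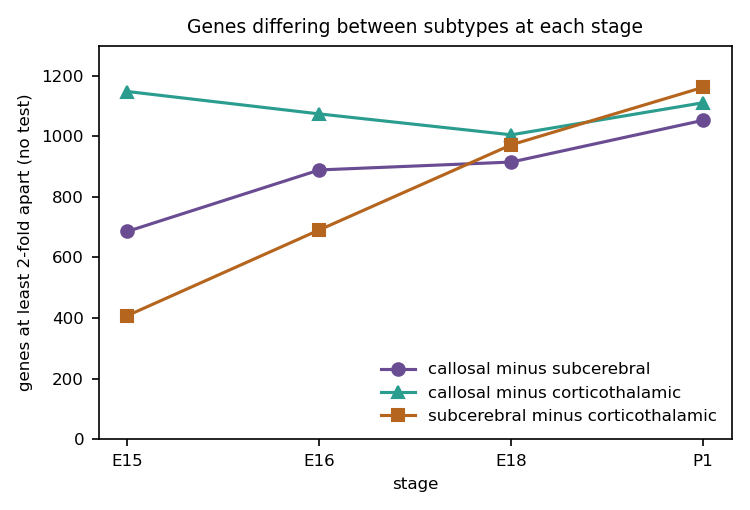
Number of genes at least 2-fold apart (no test) against stage, with 1 line per pair of subtypes. The subcerebral and corticothalamic pair goes from 408 genes at E15 to 1162 at P1, while the callosal and corticothalamic pair stays between 1005 and 1148. With a pseudocount of 0.1 these are 875 to 1856 and between 1596 and 1852.

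Genes of other cell types were present and differed between groups. Microglial genes, from the resident macrophages of the brain, were highest in the callosal value at E16, E18 and P1 in 14 of 16 cases. Csf1r, a growth factor receptor gene of that lineage, was 5.33, 2.78 and 2.86 FPKM in callosal neurons at E16, E18 and P1, and at most 0.140 FPKM in the other subtypes at any stage. C1qa, a complement gene, was 5.84, 3.09 and 2.78 FPKM in the same callosal values, and Tyrobp, an adaptor gene, 4.68, 1.76 and 1.80 FPKM. At E15 these were 0.437 FPKM for Csf1r, 0.533 FPKM for C1qa and 0.637 FPKM for Tyrobp in callosal neurons. Of the exceptions, Aif1 was above 1 FPKM in every group. Leaving out E18 ended the callosal minus subcerebral calls of C1qa, Csf1r and Tyrobp (adjusted p = 0.0557, 0.066 and 0.0512), with differences of 1.74, 1.6 and 1.5 against 1.79, 1.65 and 1.48 with all stages. It also ended the callosal minus corticothalamic call of Csf1r (adjusted p = 0.0504), with 1.58 against 1.62. Interneuron genes, from cortical inhibitory neurons, were highest in the callosal value at E15 in 16 of 21 cases. Dlx1, a homeobox gene of that lineage, was 19.99 FPKM there against 1.22 FPKM in subcerebral and 2.70 FPKM in corticothalamic neurons. Lhx6 was 16.3 against 0.616 and 1.65 FPKM, and Sst, which encodes somatostatin, 12.3 against 0.251 and 0.466 FPKM. At E16 Dlx1 was 1.53 FPKM in callosal and 6.32 FPKM in corticothalamic neurons, and at P1 Sst was 1.76 and 18.4 FPKM. As a list, interneuron genes were not called between callosal and subcerebral neurons, with 1 higher of 14 (0 adjusted over the list alone; camera adjusted p = 0.348; fry adjusted p = 0.581). Between callosal and corticothalamic neurons 1 was lower (0 adjusted over the list alone; camera adjusted p = 0.778). Its adjusted p was 0.000213 without E15 and 4.78e-05 without the E15 callosal value, and 0.646 and 0.51 with an estimated correlation.

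**Figure D4:**
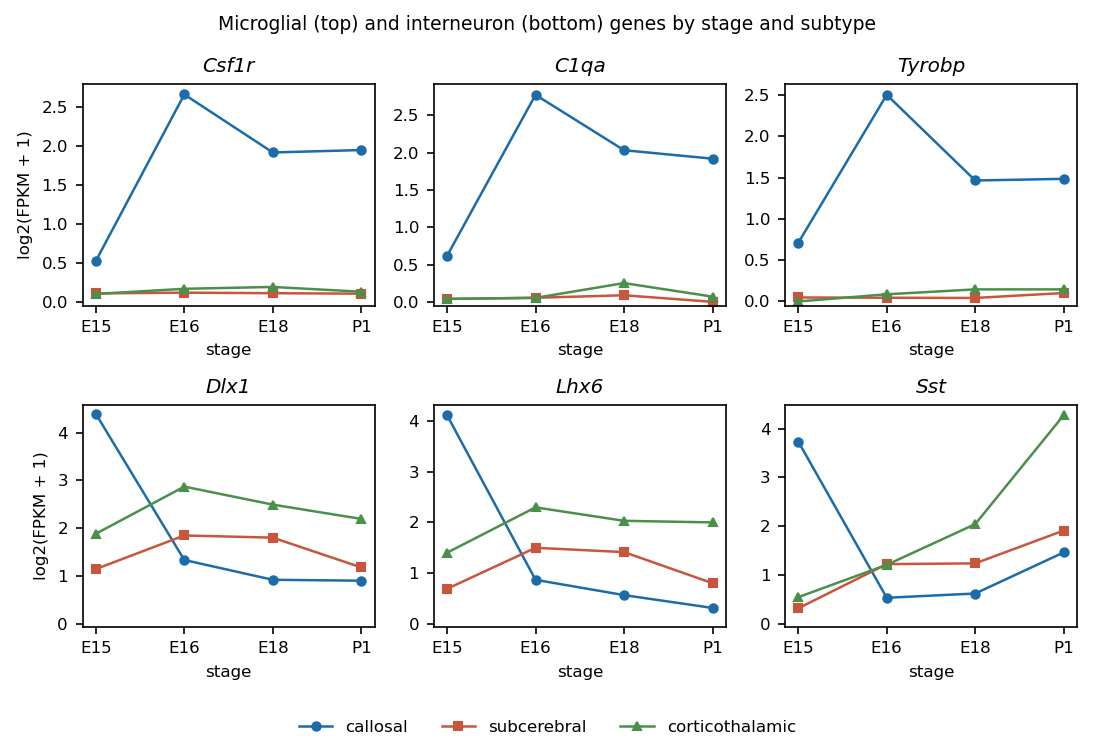
Log2(FPKM + 1) of 3 microglial genes (Csf1r, C1qa, Tyrobp) and 3 interneuron genes (Dlx1, Lhx6, Sst) at each stage, with 1 line per subtype and 1 pooled value per point. The microglial genes peak in the E16 callosal value and the interneuron genes are highest in callosal neurons at E15, with Sst at 18.4 FPKM in corticothalamic neurons at P1.

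From E15 to P1, Nrgn, which encodes the calmodulin-binding postsynaptic protein neurogranin, rose most among the genes named by the rule, by 6.38 ± 0.54 (limma adjusted p = 2.67e-05). It was 0.472, 1.39 and 3.70 FPKM in callosal, subcerebral and corticothalamic neurons at E15, and 207, 368 and 124 FPKM at P1. The tyrosine kinase gene Ptk2b rose by 5.16 ± 0.51 (limma adjusted p = 5.78e-05), the sodium pump subunit gene Atp1b1 by 4.44 ± 0.35, Npy, which encodes neuropeptide Y, by 4.38 ± 0.39, and the contactin gene Cntn6 by 4.35 ± 0.81. The sulfatase gene Sulf2 rose by 4.27 ± 0.19, Arhgdig by 4.25 ± 0.31, the GABA transporter gene Slc6a11 by 4.14 ± 0.17, the calcium sensor gene Vsnl1 by 4.08 ± 0.15 and Igfbp5 by 4.06 ± 0.56. The largest falls were those of Rspo3, which encodes a Wnt signal enhancer, at -3.51 ± 0.28 (limma adjusted p = 2.17e-05) and Nrn1, which encodes neuritin, at -3.43 ± 0.24 (limma adjusted p = 1.24e-05). Phf21b changed by -3.12 ± 0.29, AK044422 by -3.06 ± 0.15, Dpy19l1 by -3.04 ± 0.48, and the zinc finger gene Zfp521 by -3.03 ± 0.67. Ier5 changed by -2.91 ± 0.33, E330009J07Rik by -2.91 ± 0.15, the Wnt receptor gene Fzd2 by -2.90 ± 0.28 and Zfp658 by -2.87 ± 0.09. In all, 9400 genes passed, 4716 up and 4684 down, with 1376 and 973 at least 2-fold. The share of increases was 50.2%, but 45.5% with quantile normalization, 49.3% without subcerebral and 49.4% without corticothalamic neurons. Of the 20 genes named here, 19 passed whichever subtype was left out, and Zfp521 had adjusted p of 0.0684 without subcerebral and 0.0587 without corticothalamic neurons. A difference in preparation between the stages, shared by all subtypes, would pass in the same way.

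Of 29 synaptic vesicle and release genes, 22 rose from E15 to P1 and 1 fell (22 and 1 adjusted over the list alone), with the vesicle protein genes Vamp2 at 1.02 ± 0.07 and Syp at 1.17 ± 0.10 (camera adjusted p = 9.07e-05; adjusted p = 0.354 with an estimated correlation). Of 38 genes of glutamate receptors and the postsynaptic density, 21 rose and 6 fell (21 and 6 adjusted over the list alone), with the NMDA receptor gene Grin1 at 2.32 ± 0.08 and the kinase gene Camk2a at 2.23 ± 0.20 (camera adjusted p = 0.0127; adjusted p = 0.354 with an estimated correlation). Of 15 genes of GABA receptors and chloride transport, 13 rose (13 adjusted over the list alone), including Slc12a5, which encodes the chloride exporter KCC2, at 2.53 ± 0.19 (camera adjusted p = 0.000291; adjusted p = 0.508 with an estimated correlation). Voltage-gated channel genes rose in 19 of 36 cases and fell in 7 (19 and 7 adjusted over the list alone), with the pacemaker channel gene Hcn2 at 2.26 ± 0.14 (camera adjusted p = 0.0397, or 0.073 without the E15 callosal value; adjusted p = 0.354 with an estimated correlation). Nuclear respiratory chain genes rose in 74 of 87 cases and fell in 4 (76 and 4 adjusted over the list alone), with Ndufv3 at 1.43 ± 0.09 (camera adjusted p = 1.9e-11; adjusted p = 0.781 with an estimated correlation). Cholesterol synthesis genes rose in 15 of 20 cases (15 adjusted over the list alone), with Fdps at 1.96 ± 0.28 (camera adjusted p = 0.0056; adjusted p = 0.869 with an estimated correlation). Genes of proliferating cells and progenitors fell in 12 of 22 cases and rose in 2 (14 and 2 adjusted over the list alone), with the cyclin gene Ccnb2 at -1.70 ± 0.08 and the proneural gene Neurog2 at -2.63 ± 0.21 (camera adjusted p = 0.0223; adjusted p = 0.457 with an estimated correlation). Cytosolic ribosomal protein genes fell in 39 of 75 cases and rose in 1 (29 and 1 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 0.00273, or 0.869 with an estimated correlation). The shares of this list and of the progenitor list that passed were smaller than over all genes tested (9400 of 13946). Migration and early differentiation genes went both ways, with 10 up and 13 down of 30 (11 and 14 adjusted over the list alone; camera adjusted p = 0.569; fry adjusted p = 0.000387, toward a fall): Gap43, a growth cone gene, rose by 2.14, and the transcription factor gene Sox11 changed by -2.01 ± 0.11.

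**Figure D5:**
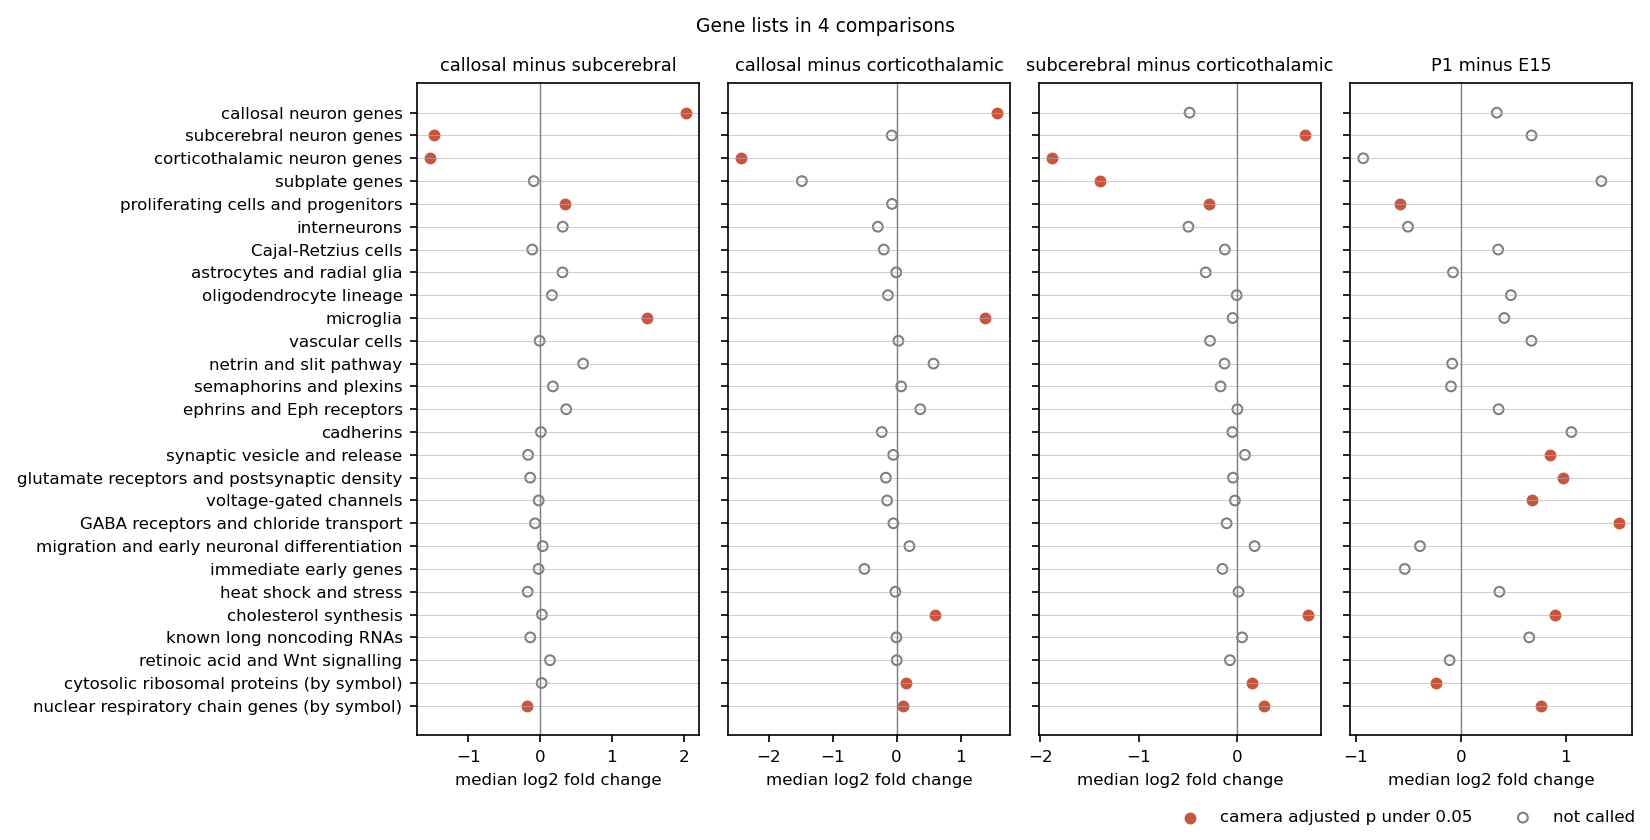
Median log2 fold change of each tested gene list in the 3 comparisons between subtypes and in P1 minus E15, with filled points where the camera adjusted p was under 0.05 at the preset correlation. The nuclear respiratory chain list has medians of 0.27 in subcerebral minus corticothalamic and 0.76 in P1 minus E15.

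Between neighbouring stages most of the genes that passed did so from E18 to P1. From E15 to E16, Lars2, which encodes mitochondrial leucyl-tRNA synthetase, rose by 4.27 ± 0.27 (limma adjusted p = 0.00127), from 9.62 to 14.7 FPKM at E15 to between 192 and 276 FPKM at E16. XLOC_002097 rose by 3.12 ± 0.25 and BC002163 by 2.77 ± 0.09, while Tmem176b changed by -2.02 ± 0.32, AK182281 by -1.96 ± 0.35 and Gm12166 by -1.76 ± 0.36. From E16 to E18, Nrgn rose by 2.44 ± 0.54, the adhesion gene Negr1 by 2.41 ± 0.33 and Sulf2 by 2.26 ± 0.19, while AK049668 changed by -2.45 ± 0.11, BC002163 by -2.44 ± 0.09 and Rspo3 by -1.61 ± 0.28. From E18 to P1, Snora28 rose by 2.31 ± 0.52 and the entry named 14-3-3 gamma by 2.23 ± 0.15, while AK044422 changed by -2.17 ± 0.15, the ubiquitin ligase gene Mid1 by -2.08 ± 0.14 and Zfp658 by -2.00 ± 0.09. Mir760 was 23.4 FPKM in callosal and 19.2 FPKM in subcerebral neurons at P1 and listed at 0 in the other groups. In all, 719 genes passed from E15 to E16 (353 up, 366 down), 620 from E16 to E18 (395 up, 225 down) and 5609 from E18 to P1 (2740 up, 2869 down). The share of increases from E16 to E18 was 63.7%, but 46.8% with quantile normalization, 0% of the 7 genes left without callosal neurons and 40% of the 5 left without subcerebral neurons. From E15 to E16 it was 49.1%, but 57.6% with median-ratio scaling and 56.3% with a pseudocount of 0.1, and it was over 50% with any 1 of the 3 subtypes left out, and without the E16 callosal value or the E15 subcerebral value. From E18 to P1 it was 48.9%, and 51.5% with the filter at 5 FPKM. The E16 minus E15 count was 9 without callosal, 6 without subcerebral and 87 without corticothalamic neurons, 89 without the E16 callosal value and 362 without the E15 subcerebral value. The E18 minus E16 count was 7, 5 and 48 without each subtype in that order, 70 without the E16 callosal value and 1877 without the E15 subcerebral value. The P1 minus E18 count was 3077 without callosal and 2257 without corticothalamic neurons. Among the genes named for each step, BC002163 in the first, AK049668 and BC002163 in the second, and 14-3-3 gamma, AK044422, Mid1 and Zfp658 in the last passed whichever subtype was left out. A difference in preparation shared by all groups of a stage would pass in the same way and cannot be told apart from development. BC002163 was 0.241 to 0.428 FPKM at E15, 7.60 to 8.81 FPKM at E16 and 0.447 to 0.851 FPKM at E18. Lars2 and XLOC_002097 had adjusted p of 0.0612 and 0.0631 without subcerebral neurons. Sulf2 had 0.0718 and Nrgn 0.283 without callosal neurons.

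Differences between subtypes changed with stage in many genes, and these values had no test. The range of a subtype difference over the 4 stages was at least 2 log2 units in 601 genes, in 213 without E15 and in 1303 with a pseudocount of 0.1. The 10 largest ranges belonged to the small RNAs and transcript identifiers Snora31, Mir677, AK182549, Snora44, Snora41, Snora75, Snora3, Mir1937b-2, AK178082 and Mir1966, each listed at 0 in 7 to 10 of the 12 groups. With small RNAs and AK identifiers left out, a choice made after the values were seen, 556 genes had such a range, led by Lpl, Tcerg1l, Sst, XLOC_003087, Sorcs1, Fosl2, Fam19a1, Arhgdib, Mdga1 and Reln. Lpl, which encodes lipoprotein lipase, went from 20.4 to 145 FPKM in callosal neurons between E15 and P1 and from 58.0 to 3.37 FPKM in subcerebral neurons. The transcription factor gene Fosl2 was 1.23 FPKM in callosal and 28.0 FPKM in subcerebral neurons at E15, and 12.4 and 2.14 FPKM at P1. Sorcs1, a sorting receptor gene, had a subcerebral minus corticothalamic difference of -0.14 at E15 and 5.66 at P1, and Arhgdib one of 0.15 and 5.64. In corticothalamic neurons the transcription factor gene Tbr1 went from 315 to 156 FPKM between E15 and P1, against 223 to 15.7 FPKM in subcerebral neurons. Fezf2 went from 366 to 127 FPKM in subcerebral, 125 to 65.8 FPKM in corticothalamic and 65.9 to 11.4 FPKM in callosal neurons.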

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

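The tests of independent scatter and the E15 ratio tests were chosen after the results were seen, while the tests on the second microglial and interneuron lists and on other splits were written before. Subtype differences that turned direction between stages were looked for in the deposited values, which have no replicates, so none of these differences was tested. The rule's own genes with opposite directions had values listed at 0 and have no fold, so the 4 genes below were chosen after their values were seen.

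Lpl was higher in subcerebral neurons at E15 (callosal minus subcerebral -1.46) and higher in callosal neurons from E16 on (1.11, 3.79 and 5.06), a range of 6.52. Sst had a callosal minus corticothalamic difference of 3.18 at E15 and -2.81 at P1, a range of 5.99. Sst is an interneuron gene, and most interneuron genes were highest in the E15 callosal value. Its turn may therefore not be one of projection neurons. Fosl2 went from -3.70 at E15 to 2.1 at P1 in callosal minus subcerebral, a range of 5.8. Reln, which encodes the extracellular protein reelin, went from 1.68 to -3.59 in the same comparison, a range of 5.27. Its difference was positive at E15 alone (-2.05 at E16 and -2.58 at E18), as that of Sst against corticothalamic neurons was. Whether the turn of Reln is one of projection neurons was not tested.

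Microglial genes were higher in the callosal values at E16, E18 and P1. Low values scattering independently would make about 4% of genes highest in callosal neurons at all 3 stages, while 78.9% of the genes of both microglial lists were (30 of 38). This argues against such scatter but is not a clean test of it. The first list is the one in which the pattern was seen. Most of the second-list genes used, such as Irf8 and Siglech, reached the cutoff of 0.5 FPKM only in a callosal value, so 4% is too low for them. Microglia among the sorted callosal cells may be a source, but the second list gave 63.6% of genes at least 2-fold higher (14 of 22), between the bounds of 75% and 50% set for and against it. Among the genes that were, all but Mpeg1 reached 0.5 FPKM only in a callosal value. Their choice favoured such a result, so this percentage is not an independent test and decides nothing. Of the misses, Cd68, Lgmn, Slc2a5 and Plek were under 2-fold apart between subtypes at each of these stages (Cd68 was 6.55, 3.66 and 4.85 FPKM at E18), and Lyz2 missed at E18 alone. Olfml3 was highest in corticothalamic neurons, and Lcp1 and Inpp5d were higher in subcerebral than in callosal neurons at E18 and P1 (Inpp5d was 1.08 and 0.318 FPKM at E18). A difference between subtypes in their own expression was not tested and stays open, and the labels do not give the sort markers.

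Interneuron genes were higher in the E15 callosal value than in the other E15 values. Independent scatter of low values would put about 33% of genes highest there, while 76% of the genes of both interneuron lists were (19 of 25, binomial p = 0.00544 after multiplying by 348 combinations of list and column). This argues against such scatter. Most of these genes came from the first list, in which the pattern was seen, and Elfn1 reached the cutoff of 0.5 FPKM at E15 only in the callosal value. Interneurons among the cells sorted as callosal at E15 may be the source: on a second list 75% of genes were at least 2-fold higher, which is 3 of 4 (Npas1, Elfn1 and Sox6, but not Cxcr7) and a thin base. The choice of Elfn1 through its callosal value favoured its result here too, and the bound of 75% was met only with it. Stage and subtype as a biological cause stay open as untested.

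Subcerebral and corticothalamic values lay closest at E15. A share of corticothalamic cells in the E15 subcerebral sort would set a floor under the ratio of subcerebral to corticothalamic value of all corticothalamic genes. The test took a single ratio for all of them, which holds only where subcerebral cells lack the gene. It found 24.4% (11 of 45) under 0.5 of the median of 0.493, which alone decides little. Ratios over the 45 genes ran from 0.035 for Kcnab1 and 0.037 for Kitl to 1.52 for Dcc. The lowest ratios leave room only for a small share. From ratios of at most 0.25, as at each later stage, that share cannot give a median of 0.493. This excludes such a mixture as the whole cause. Subcerebral cells in the E15 corticothalamic sort are excluded as the whole cause too. The 14 subcerebral genes had a median E15 ratio of corticothalamic to subcerebral value of 0.208. With that share of subcerebral cells taken out of the corticothalamic value, 73.3% of the corticothalamic genes (33 of 45) stayed above a ratio of 0.25, against at most 0.25 at each later stage by their choice. A later divergence of the subtypes stays open as a biological explanation and was not tested, and a partial mixture of cells may contribute.

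Real groupings were set against other splits of the values, each refitted with all 12 values. For callosal against subcerebral, callosal against corticothalamic and subcerebral against corticothalamic neurons, 1 of 35 splits of the 8 values, the real one, gave as many genes (4093, 4361 and 3835, against 1 gene in the highest other split of each). Most of the other splits mix stages, which the values are matched by, so the bound of 5% set for these 35 splits was wrong. Exchanging labels within stages leaves 8 splits, which are too few for a share under 5%, with 1, 0 and 0 genes in the highest other. For E16 minus E15, E18 minus E16, P1 minus E18 and P1 minus E15, 1 of 10 splits, the real one, gave as many (719, 620, 5609 and 9400, against 0, 0, 1 and 0), and 10 splits, or the 4 within subtypes, are too few for a share under 5%. Among 100 regroupings within stages, the real one included and the others drawn, 1 (the real one) gave as many callosal-highest genes as the real 985. For subcerebral-highest genes 2, the real one among them, gave as many as 580, and for corticothalamic-highest genes 1 (the real one) gave as many as 849. The highest other regrouping had 781, which lies above the real subcerebral count. The shares lie under 5%, which argues against values that differ between no subtypes within a stage. Each regrouping dealt the labels of all subtypes, and any dealt group with as many genes was counted. The shares therefore cannot decide whether a given subtype, such as the subcerebral, stands apart from each of the others. For subcerebral against corticothalamic neurons alone, the 8 splits within stages are too few to decide.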

How the results depend on the processing

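The fits without the E15 callosal, E16 callosal or E15 subcerebral value, and the interaction without short RNA and AK identifiers, were chosen after the data were seen. No paired analysis was possible because the columns carry no replicate numbers, so the replicate and letter blocks, each library left out, fits on the 6 libraries of a stage, and trend and robust moderation for untested values were not run. Of 6029 values under the alternatives, limited to the named genes and list members reported here, 5596 kept their direction and side of the threshold, 433 lost the threshold and 0 reversed. Most of these genes were chosen because they passed. The largest differences also had to have the same sign at every stage or subtype, so leaving 1 out could not reverse them. The 0 therefore says little about the other genes tested. Median-ratio scaling, quantile normalization, both filters and moderation without trend left every count within 1.5 times of the main one. A left-out stage or subtype removes values and residual degrees of freedom, and counts mostly fell. Without E15, which removes as many values as any other stage, the counts of the subtype comparisons and of highest genes rose. In callosal minus subcerebral the count went from 4093 to 6179, against 1117 without E16. The loss of values alone therefore does not account for the changes. Without the E15 subcerebral value alone the same count was 5981. Genes with a subtype range of at least 2 log2 units fell from 601 to 213 without E15, against 406 to 563 without another stage. Such genes have a large error in this fit, so a smaller residual went with the rise. Why E15 differed was not tested. Depth is unknown, so its limits cannot be given.

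With each stage left out, counts ranged from 1016 to 6179 in callosal minus subcerebral, 1868 to 4556 in callosal minus corticothalamic, 251 to 6258 in subcerebral minus corticothalamic, 311 to 1106 for callosal-highest, 20 to 1783 for subcerebral-highest and 119 to 1143 for corticothalamic-highest genes, and 213 to 563 for the interaction. With each subtype left out they ranged from 6 to 87 in E16 minus E15, 5 to 48 in E18 minus E16, 2257 to 4551 in P1 minus E18 and 7676 to 8054 in P1 minus E15. A fit on the 8 values of the compared subtypes gave 2606 in callosal minus subcerebral and 2409 in subcerebral minus corticothalamic. Without the E15 callosal value the subcerebral-highest count was 910. Without the E16 callosal value the counts were 2174 and 2812 in callosal minus subcerebral and corticothalamic, 89 in E16 minus E15, 70 in E18 minus E16, 542 callosal-highest and 254 subcerebral-highest. Without the E15 subcerebral value they were 6132 in subcerebral minus corticothalamic, 362 in E16 minus E15, 1877 in E18 minus E16 and 1693 subcerebral-highest. A pseudocount of 0.1, which widens folds of low genes, gave 1305, 1852 and 875 genes at least 2-fold apart at E15 (callosal minus subcerebral, callosal minus corticothalamic, subcerebral minus corticothalamic), 1538, 1730 and 1252 at E16, 1593, 1596 and 1528 at E18, 1826, 1676 and 1856 at P1, and 1303 for the interaction. List calls numbered 0 with an estimated correlation and 45 with fry, against 27.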

Other observations

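Several fixed lists not yet described held genes that differed between subtypes. Of 11 genes of astrocytes and radial glia, 4 were higher and 3 lower in callosal than in subcerebral neurons (4 and 3 adjusted over the list alone; camera adjusted p = 0.591), with the matricellular gene Sparcl1 at -2.09 ± 0.26. Of 6 oligodendrocyte lineage genes, 2 rose and 2 fell from E15 to P1 (2 and 2 adjusted over the list alone; camera adjusted p = 0.731), and fry called them as higher at P1 (fry adjusted p = 0.0164), with Lhfpl3 at 1.70 ± 0.14. Of 5 Cajal-Retzius genes, 2 were higher in callosal than in subcerebral neurons (2 adjusted over the list alone; camera adjusted p = 0.799), and Nhlh2, a helix-loop-helix gene, differed by -0.95 ± 0.17 in callosal minus corticothalamic. Of 7 vascular genes, 4 rose from E15 to P1 (4 adjusted over the list alone; camera adjusted p = 0.127; fry adjusted p = 0.00661), including the basement membrane collagen gene Col4a1 at 0.72 ± 0.09. Of the red blood cell list only Hba-a2, an alpha globin gene, was tested, and it lay between 2.11 and 9.11 FPKM in the 12 groups. Of the mitochondrially encoded genes only mt-Nd4 was in the table, between 992 and 2065 FPKM.

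Among known long noncoding RNAs, 3 of 12 were higher and 2 lower in callosal than in subcerebral neurons (3 and 3 adjusted over the list alone; camera adjusted p = 0.797; fry adjusted p = 0.0499, toward lower). The imprinted transcripts Meg3 and Rian differed by -1.90 ± 0.28 and -1.90 ± 0.25. Of 20 retinoic acid and Wnt signalling genes, 2 were higher and 5 lower in subcerebral than in corticothalamic neurons (2 and 6 adjusted over the list alone; camera adjusted p = 0.473; fry adjusted p = 0.027, toward lower), including the Wnt gene Wnt7a at -1.42 ± 0.16 and the Wnt inhibitor gene Sfrp2 at -2.16 ± 0.27. Of 15 immediate early genes, which respond to activity, 3 rose and 6 fell from E15 to P1 (3 and 6 adjusted over the list alone; camera adjusted p = 0.405; fry adjusted p = 0.0329, toward a fall), with the phosphatase gene Dusp1 at -1.98 ± 0.16 and Fos at 1.08. Of 17 heat shock and stress genes, 9 rose and 6 fell (10 and 6 adjusted over the list alone; camera adjusted p = 0.629), with the chaperone gene Hspa1b at 1.05 ± 0.13 and Ddit4 at -1.74 ± 0.25. The mean of that list was 0.10, and -0.01 with quantile normalization.

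Loci known only by an assembly identifier passed less often by share than other genes, with no test of the difference: 26.3% against 29.6% in callosal minus subcerebral, 30.1% against 31.4% in callosal minus corticothalamic, 24% against 27.8% in subcerebral minus corticothalamic and 60.7% against 67.9% in P1 minus E15. Median, mean and camera direction had different signs in 17 of the 108 list tests, and in 0 of the 27 called. Cytosolic ribosomal protein genes were not called in callosal minus subcerebral (camera adjusted p = 0.731) and were called with quantile normalization (0.0275, or 0.911 there with an estimated correlation).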
